A study of Mus musculus with 6 samples.

How the data were processed

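ATAC-seq, in which a transposase cuts and tags accessible DNA, was applied to LT-HSC, ST-HSC and MPP cells sorted from the bone marrow of wild-type C57BL/6 mice. The labels give 2 libraries for each of the 3 populations, 6 in all, and do not say whether the libraries of a population came from separate animals or sorts, so spread between them may be technical. The sort used lineage markers, Sca1, c-Kit, CD150 and CD48, per the labels' protocols. The gate of each population is not given in the sources used here.

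Bowtie2, HOMER and the mouse build mm10 are named in the submitters' processing notes, without versions or settings. How reads were filtered, shifted or freed of duplicates is not given in the sources used here. One peak list per population was used. Each entry joins a pair of overlapping peaks, one from each of 2 peak sets called separately, and almost all single peaks were 151 bp wide. The overlap, the only deposited column of another kind (unit: other), equalled in every entry the overlap computed from the coordinates. A listed peak is therefore a peak found in both libraries of a population, and peaks found in 1 library alone were not analysed here. Each entry also carries 1 value per library. These deposited signal values are the authors' and were used as given. Within a library all values under 10 were whole multiples of a single step, to a tolerance of 0.0055, as a scaled tag count would be. The scale is not stated. If values were scaled to 10 M tags, the steps correspond to 180 and 41.0 M tags for the first and second LT-HSC library, 206 and 38.9 M for ST-HSC, and 208 and 19.8 M for MPP. The first library of each list was thus the deeper. The columns carry no replicate number, so libraries are named first and second by their place in the list. The weakest listed peaks held between 7 and 27 steps, and a call near that floor rests on few tags.

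The interval of a listed peak was the span of its pair. The 3 lists were merged into regions wherever peaks overlapped by at least 1 bp, and each region was classed by the lists that held it. A region missing from a list may lie below that list's calling threshold, so regions are described as found or not found in a list. Chance overlap was taken from 100 seeded random placements of the peaks on the same chromosomes. Intervals of shares are 95% binomial intervals (Wilson, or exact where said) and cover counting error only. Because every population has a single joint list, counts of peaks and regions carry no SD and no test between populations.

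Genes came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, with 49943 genes on placed chromosomes, of which 21887 are protein-coding. The table gives gene start and end but no strand, exons or transcription start sites. Distance to either end of a gene, called a gene boundary, therefore replaced distance to the transcription start, and exons, introns and UTRs were not annotated. Regions were assigned to a protein-coding gene when their centre lay in its body or within 20 kb of it. A boundary peak is one centred within 1 kb of either end. The 15 gene lists, their 304 genes, the thresholds, the named-gene rule and most alternatives were fixed before the data were examined. The table held 303 of these genes, 301 of them as protein-coding genes on placed chromosomes. Its place for Hbb-b1 (chromosome 7, 38285 to 39684) was used as given, and that gene's window held 0 regions. The lists were HSC identity, lymphoid priming, myeloid, megakaryocyte-erythroid, cell cycle, interferon response, Hox and TALE, chromatin regulators, sorting markers, housekeeping, mature T and NK cells, mature B cells, mature granulocytes and macrophages, stroma and endothelium, and tissue not in marrow. For each list and pair of populations, the share of the list's regions found in each population was computed, and the difference in percentage points was placed among 10000 random lists of as many protein-coding genes, matched on their number of regions. Percentiles outside 2.5 to 97.5 are called beyond the bounds. They describe these lists and are not p-values. The matching did not cover the share found in the earlier population. Genes with a boundary peak were counted per list and set beside 10000 random lists without matching. The change in that count between populations was added after the counts were seen, and its random lists were not matched on the starting count.

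The rule for named genes had 5 parts. For each pair, the first 6 lists gave the 2 genes with most regions found only in the earlier and the 2 with most only in the later population, with at least 2 such regions and more than of the opposite kind. For each pair, the 5 protein-coding genes with the largest net excess in either direction were taken from all genes. This net count was not adjusted for gene length, and a long gene has room for more regions. Kit, Ly6a, Slamf1, Cd48 and Ptprc of the sorting marker list were always given. Genes of the lists with a boundary peak in some but not all populations could be named, at most 8 per pair and list. For each population, the 3 regions found in its list alone with the highest values were named with the nearest gene boundary. Some genes that the rule takes are not reported here.

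The plan used values only within their own list. Since the lists held a value for each library, a comparison was added after the files were seen. In 11947 regions on placed chromosomes found in all 3 lists, log2 values were centred on each library's median and fitted with limma, with a variance trend, 2 libraries per population and no block. Adjusted p-values are Benjamini-Hochberg over these regions, with a threshold of 0.05, and gene lists were tested with camera. The lists were made separately and the authors state no scaling between them, so this comparison is kept apart from the counts. A planned motif analysis needs the genome sequence and was not run.

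Alternatives to the overlap rule, the peak threshold, the gene windows, the chromosomes and the matching were tried, as were other scalings, fits with each library left out and a fit with the column position of the library as a block. Steps that compute statistics across many genes or regions were tested on simulated data. With regions added to 200 lists of 25 genes, LT-HSC against MPP, over 21887 genes, 24.5% of the lists passed the bounds when 20% of missing regions were added, 6.0% when 10% were, and 2.0% with none. In simulated values for MPP against LT-HSC over 11947 regions, limma without a block recovered 0 of 200 changed regions at a log2 change of 1, 179 at 2 and 200 at 3. These values were drawn without an effect of column position, so this recovery need not hold in the real data. There the same fit passed 0 regions, though a region inside Slc22a3 changed by -2.42 (log2, limma adjusted p = 0.0587). Computation used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and R 4.3.3 with limma 3.58.1. Figures were drawn with Matplotlib 3.10.9.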

Results

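Accessible chromatin was mapped by ATAC-seq in long-term haematopoietic stem cells (LT-HSC), short-term haematopoietic stem cells (ST-HSC) and multipotent progenitors (MPP) sorted from mouse bone marrow, which follow each other at the start of blood cell differentiation. Each population had 2 libraries, and the deposited list of each population holds the peaks found in both. The MPP list was the longest with 33585 peaks, followed by LT-HSC with 22285 and ST-HSC with 17249. They covered 6.07, 3.99 and 3.08 Mb of the mm10 genome. Values of the 2 libraries of a list correlated across peaks with r = 0.838 in LT-HSC, 0.799 in ST-HSC and 0.840 in MPP on the log2 scale. The Spearman correlations were 0.710, 0.712 and 0.777. Peaks are not independent replicates, and each population has a single joint list, so differences between the counts below have no replicate error. The libraries differed in depth. If the values are scaled to 10 M tags, the first libraries held 180 M tags in LT-HSC, 206 M in ST-HSC and 208 M in MPP, against 41.0, 38.9 and 19.8 M in the second ones. At least 150950 and 44684 peaks were called in the first and second MPP library, 103783 and 40922 in LT-HSC, and 113442 and 48913 in ST-HSC, judged by the highest peak number per chromosome. By these numbers ST-HSC had more called peaks than LT-HSC in both libraries but the shorter list. At most 75.2% of the peaks called in the second MPP library were listed, 54.5% in LT-HSC and 35.3% in ST-HSC. List length therefore also depends on how many calls the 2 libraries of a population share.

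The lists were first compared as a whole, to ask how much accessible chromatin the populations share. They merged into 40684 regions, of which 11993 (29.5%) were found in all 3 lists. The largest class was 14585 regions (35.8%) found only in the MPP list. A further 4090 regions were found only in the LT-HSC list and 1567 only in the ST-HSC list. LT-HSC shared 4760 regions with MPP that ST-HSC lacked, ST-HSC shared 2247 with MPP that LT-HSC lacked, and 1442 regions were found in LT-HSC and ST-HSC but not in MPP. These sizes follow the lengths of the lists. With each list held to its strongest 17249 peaks, the regions found in a single list numbered 3404 for MPP, 3153 for LT-HSC and 3054 for ST-HSC, and 10234 were found in all 3. The order of the classes of 2 lists then turned, with 2106 regions in LT-HSC and ST-HSC, 1855 in ST-HSC and MPP and 1756 in LT-HSC and MPP.

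**Figure D1:**
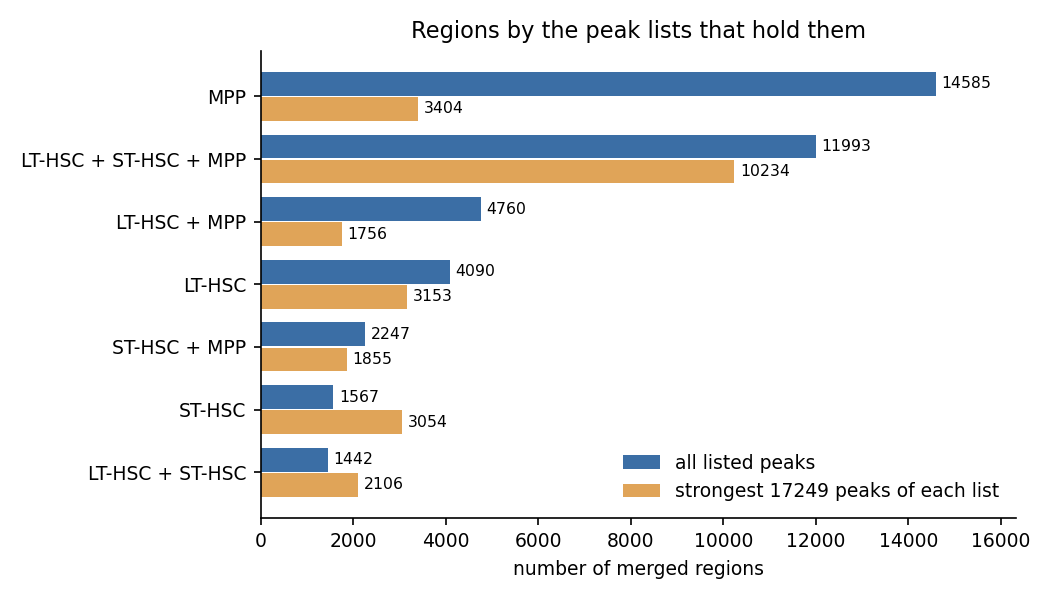
Number of merged regions (horizontal axis) in each combination of peak lists (vertical axis), for all listed peaks (blue bars) and for the strongest 17249 peaks of each list (orange bars). The 14585 regions of the MPP list alone fall to 3404 when the lists have equal length.

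Regions found in a single list were the weaker ones. In LT-HSC the median of the authors' values, taken as the geometric mean of both libraries, was 3.39 in regions found in that list alone, 3.93 in regions of 2 lists and 6.38 in regions of all 3. The corresponding medians were 3.44, 4.10 and 6.71 in ST-HSC and 5.06, 7.00 and 12.9 in MPP. Each peak's value is the authors' own and is ranked here only within its list.

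Regions found in all 3 lists and those found in a single list also differed in where they lay. Regions found in all 3 lists were close to genes' ends, with 55.0% (95% interval 54.1% to 55.9%, Wilson) within 1 kb of a gene boundary, against 6.27% of random positions. This share was 19.9% (18.7% to 21.1%) for regions found only in LT-HSC, 20.2% (18.2% to 22.2%) for ST-HSC and 22.0% (21.4% to 22.7%) for MPP. Of the regions found only in MPP, 47.7% lay elsewhere in gene bodies and 30.2% between genes, whereas 40.6% of those found only in LT-HSC lay between genes. In the full lists, 42.6% of LT-HSC, 45.9% of ST-HSC and 36.0% of MPP peaks were within 1 kb of a gene boundary. Windows of another size moved these shares but not their order between regions of all 3 lists and regions of a single list. The shares were not compared at equal peak value, and regions of a single list were the weaker ones.

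The first comparison, LT-HSC against ST-HSC, sets long-term beside short-term stem cells. The lists shared 13435 regions, 51.5% of those found in either, where random placement gave 62.8 overlapping peaks on average and 82 at most. A further 8850 regions were found only in LT-HSC and 3814 only in ST-HSC, against 4909 each with equal list lengths. In this and the later comparisons, such equal counts follow from the cut to equal length and are no observation. Over all protein-coding genes, the largest net excess toward LT-HSC was at Pde4d, a cAMP phosphodiesterase gene (chromosome 13, 108654177 to 109955969), with 18 regions in LT-HSC and 7 in ST-HSC. It was followed by Cntnap2, Camta1, Rab3il1 and Tpd52. Toward ST-HSC the excess was largest at Ptprm (1 and 6 regions in LT-HSC and ST-HSC), Ear1, Hapln1, Klrd1 and Adgrl3. Here and in the later comparisons, these rankings used the full lists and were not adjusted for gene length.

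Among genes tied to stem cell identity, some had more regions in LT-HSC. Mecom, a transcription factor needed for stem cell maintenance, had 5 regions in LT-HSC and 3 in ST-HSC, and the ETS factor gene Erg had 2 and 0. Taken as a list, the HSC identity genes had 50.8% of their 130 regions in LT-HSC and 35.4% in ST-HSC. This difference of -15.4 points lay at percentile 34.4 of random lists, within the bounds. Boundary peaks were found at 13 of its 30 genes in LT-HSC and 9 in ST-HSC, and the genes with such a peak in LT-HSC but not ST-HSC were Tek, Clec1a, Hoxa10 and Cdkn1c. Tek encodes an angiopoietin receptor of stem cells and endothelium, and Cdkn1c a cell cycle inhibitor. At lineage genes LT-HSC had more regions than ST-HSC at the cytokine receptor gene Flt3 (8 against 4), at the B cell factor gene Ebf1 (2 against 0), at the lysozyme gene Lyz2 (3 against 0), and at the megakaryocytic and erythroid genes Fli1 and Ank1 (4 against 2 each). Lef1 had 1 region in LT-HSC and 3 in ST-HSC. In the interferon list, Ifit1 had 2 regions against 0, and in the cell cycle list Cdk4 and Cdk6 had 4 against 3 each.

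In the main setting, only the chromatin regulator list passed the bounds between LT-HSC and ST-HSC. Its genes had 62.9% of 105 regions in LT-HSC and 38.1% in ST-HSC, a difference of -24.8 points at percentile 2.42. Genes with a boundary peak in LT-HSC but not ST-HSC included Tet1 and Arid1a. A boundary peak was found in ST-HSC but not LT-HSC at Bmi1. With equal list lengths the difference was -23.5 points, also beyond the bounds (percentile 0.625). The list lay within the bounds at percentile 11.2 in windows of gene body plus 100 kb, 8.74 by nearest boundary within 100 kb, 5.09 for regions over 1 kb from a boundary and 4.79 among unmatched random lists. The megakaryocyte-erythroid list, with 61.5% of 78 regions in LT-HSC and 37.2% in ST-HSC, stayed within the bounds (percentile 4.34) but passed by nearest boundary within 100 kb (2.17). Hox and TALE genes passed with gene body plus 100 kb (0.84). Tissue not in marrow, the lower reference, passed the upper bound with equal list lengths (44.4 points, percentile 99.4), with gene body plus 100 kb (98.2) and over 1 kb from a boundary (98.1).

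The second comparison, ST-HSC against MPP, sets short-term stem cells beside progenitors. The lists shared 14240 regions, 38.9% of those found in either, against 87.4 overlapping peaks on average and 114 at most by random placement. Of the rest, 19345 regions were found only in MPP and 3009 only in ST-HSC, against 5160 each with equal list lengths. Bach2, a transcriptional repressor active in lymphocytes, had the largest net excess toward MPP with 1 region in ST-HSC and 20 in MPP (chromosome 4, 32238413 to 32586109). It was followed by Arhgap26 (5 and 21 regions) and by Tns1, Zfp704 and Kctd1, which had no region in ST-HSC and 15, 15 and 14 in MPP. Toward ST-HSC the largest excess was at Nav3 (8 and 4 regions), Skap2 (3 and 0), Acer2 (5 and 2), Kcnip4 (4 and 1) and Ndst3 (4 and 1).

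Myeloid genes had a larger difference in share between ST-HSC and MPP than most random lists. They had 29.0% of their 62 regions in ST-HSC and 90.3% in MPP, a difference of 61.3 points at percentile 99.5. The random lists were not matched on the ST-HSC share. The MPP share was also 90.8% for HSC identity and 92.0% for cell cycle genes. The percentiles at this step therefore do not separate a gain in MPP from a low ST-HSC share. The stem cell and progenitor antigen gene Cd34 had 3 regions in ST-HSC and 8 in MPP, and Spi1, which encodes the myeloid and B cell factor PU.1, had 2 and 6. Hox and TALE homeobox genes had 20.3% of regions in ST-HSC and 89.8% in MPP, at percentile 100 of random lists. Windows of neighbouring Hox genes overlap, so its 59 gene-region pairs are 33 separate regions, 12 of them in ST-HSC and 30 in MPP. The percentile counts such shared regions more than once. Genes of stroma and endothelium, a list of other marrow cells, also passed the bounds, with 16.1% of 31 regions in ST-HSC and 87.1% in MPP (percentile 99.8). With equal list lengths the myeloid difference was 21.9 points (percentile 93.7) and that of Hox and TALE genes -5.56 points (percentile 21.0), whereas stroma and endothelium stayed beyond the bounds at 41.7 points (percentile 99.5). By nearest boundary within 100 kb the 3 lists lay at percentiles 83.2, 64.5 and 99.4, for regions over 1 kb from a boundary at 85.4, 83.5 and 98.1, and with gene body plus 100 kb at 99.0, 100 and 98.4.

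In the main setting, the other lists stayed within the bounds at this step. HSC identity genes had 35.4% of regions in ST-HSC and 90.8% in MPP (percentile 96.8; 5.71 points at percentile 35.6 with equal list lengths), with 3 regions of Mecom in ST-HSC and 13 in MPP and 5 and 11 of Meis1. Ndn, which encodes the growth suppressor necdin, had 2 regions in ST-HSC and none in MPP. Lymphoid priming genes had 42.1% and 85.3% (percentile 47.0), with 0 and 5 regions at Ebf1 and 4 and 9 at Flt3. Megakaryocyte-erythroid genes had 37.2% and 89.7% (percentile 90.1), with 2 and 9 regions at Fli1 and 2 and 7 at Ank1. Cell cycle genes had 52.3% and 92.0% (percentile 30.3), with 3 and 10 regions at Cdk6 and 0 and 4 at the cell cycle inhibitor gene Cdkn1a. Interferon response genes had 48.3% and 89.7% (percentile 47.4), with 1 and 4 regions at Ifit2 and 0 and 3 at Ifit3.

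The third comparison, LT-HSC against MPP, sets the ends of the series side by side. The lists shared 16753 regions, 42.8% of those found in either, against 113 overlapping peaks on average and 137 at most by random placement. Regions found only in MPP numbered 16832, and 5532 were found only in LT-HSC, against 5259 each with equal list lengths. Toward MPP the largest net excess was at Tns1 (1 region in LT-HSC and 15 in MPP), Bach2 (7 and 20), Zfp704 (3 and 15), Ppargc1a (7 and 19) and Med12l (8 and 20). Toward LT-HSC it was at Nav3 (9 and 4), Itgbl1 (4 and 0), Dmd (5 and 1), Mrps28 (5 and 1) and Cntnap5b (6 and 2).

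Myeloid and lymphoid genes had more boundary peaks in MPP than in LT-HSC. Among 22 myeloid genes, 4 had a boundary peak in LT-HSC, 4 in ST-HSC and 10 in MPP. The 6 that had one in MPP but not LT-HSC were Cebpb, Irf8, Prtn3, Gfi1, Itgam and Klf4, which include factors of granulocyte and monocyte development. Among 25 lymphoid priming genes the counts were 5, 5 and 11, and the 6 genes with a boundary peak in MPP but not LT-HSC included Rag1, Ebf1, Ikzf1, Il12a and Satb1. No gene of these lists had a boundary peak in LT-HSC and lacked it in MPP. The net gain of 6 genes lay at percentile 99.7 of random lists for myeloid and 99.3 for lymphoid priming genes, where the random mean was 1.20 and 1.38 genes. The random lists were not matched on the LT-HSC count. Against random lists that count lay at percentile 1.825 for myeloid and 2.165 for lymphoid priming genes. Both lists thus had more genes free to gain a peak than most random lists. In MPP their counts lay at percentiles 50.3 and 43.5. The percentiles of the net gain therefore do not separate a gain particular to these lists from their low start. Changes in genes with a boundary peak are not independent within a list, whose comparisons share populations. Of 45 such changes, 3 passed the bounds, with 2.25 expected by chance. The comparison was chosen after the counts were seen. The third was the interferon response list between ST-HSC and MPP, with 10 and 16 of 19 genes (percentile 98.4), where Irf7, Ifit3, Ifi44, Ddx58, Ifit1 and Xaf1 had a boundary peak only in MPP of this pair. The lymphoid gain was 2 genes (percentile 69.5) with a 500 bp window and 5 (96.5) with a 2 kb window, while the other 2 stayed beyond the bounds with both windows. With equal list lengths the lymphoid gain was 3 genes and kept its call (percentile 98.9), and the myeloid gain was 1 gene (84.7) and the interferon gain 1 gene (79.3).

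HSC identity genes had boundary peaks at 13 of 30 genes in LT-HSC and 12 in MPP. Tek, Clec1a and Ndn had one in LT-HSC but not MPP, and Tal1 and Egr1 in MPP but not LT-HSC. Cell cycle genes had boundary peaks throughout, at 18 of 23 genes in LT-HSC, 18 in ST-HSC and 19 in MPP, the added gene being the mitotic kinase gene Plk1. Megakaryocyte-erythroid genes had 8, 5 and 10 of 24, with Itga2b, Itgb3, Gp9 and Ank1 found in MPP alone and Gp1ba in LT-HSC alone. With equal list lengths these counts were 7, 5 and 3, and the change from LT-HSC to MPP was -4 genes, beyond the bounds (percentile 1.14). Housekeeping genes, the upper reference, had 17, 16 and 17 of 20, and genes of tissues not in marrow, the lower one, had 3, 1 and 3 of 15. Over all protein-coding genes the share with a boundary peak was 40.0% in LT-HSC, 34.4% in ST-HSC and 45.5% in MPP.

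**Figure D2:**
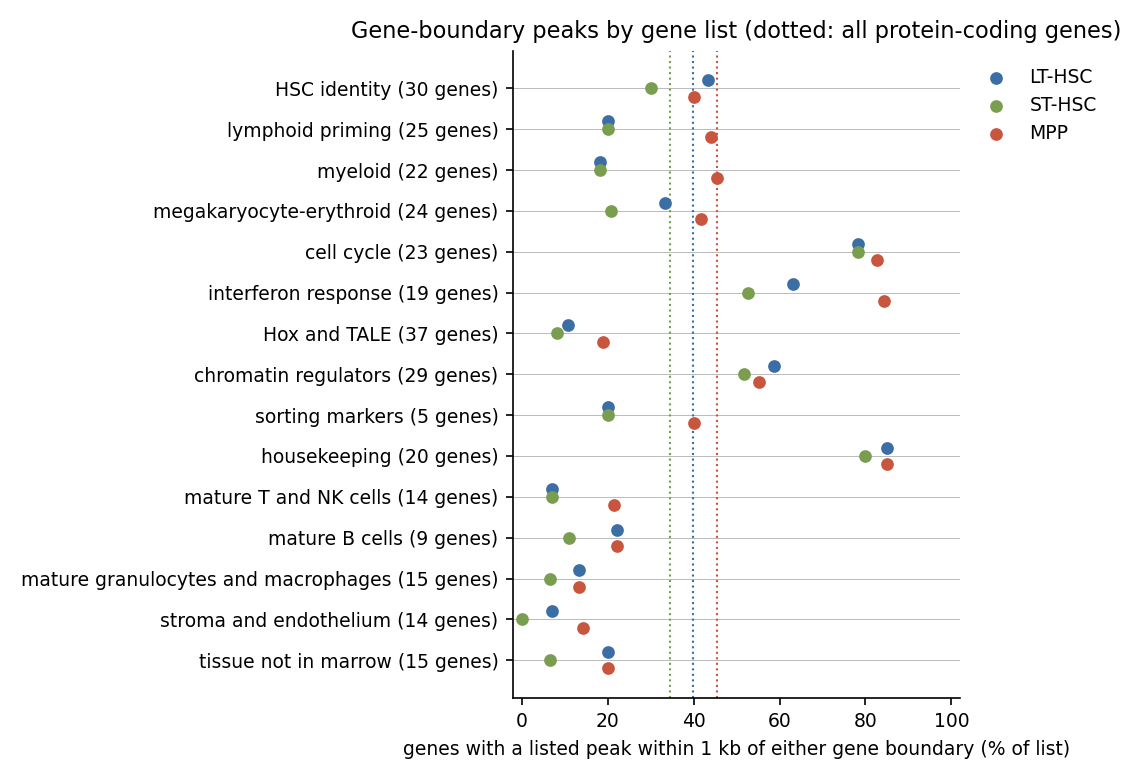
Percentage of each list's genes with a listed peak within 1 kb of either gene boundary (horizontal axis) in LT-HSC (blue), ST-HSC (green) and MPP (red), by gene list (vertical axis), with dotted lines for all protein-coding genes. Myeloid genes number 4, 4 and 10 of 22, and lymphoid priming genes 5, 5 and 11 of 25.

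Counted over all regions of the gene window, the myeloid list again passed the bounds between LT-HSC and MPP, with 43.5% of regions in LT-HSC and 90.3% in MPP (46.8 points, percentile 99.0). Cd34 had 3 and 8 regions, and Elane, the neutrophil elastase gene, had 0 and 3. Hox and TALE genes passed with 40.7% and 89.8% (49.2 points, percentile 99.5). This percentile too counts regions of overlapping windows more than once. Of the list's 33 separate regions, 15 were found in LT-HSC and 30 in MPP. Housekeeping genes lay below the bounds with 80.0% and 86.7% of 60 regions (6.67 points, percentile 1.47). With 80.0% in LT-HSC, they had little room to rise. The random lists were not matched on the LT-HSC share. The percentiles of these 3 lists therefore do not separate a change in MPP from the share in LT-HSC. Of all 45 list comparisons 7 passed the bounds, where the bounds alone would give 2.25 by chance. The comparisons of a list share populations and are not independent. Myeloid genes and Hox and TALE genes count among the 7 in both comparisons with MPP. With equal list lengths the myeloid difference was 12.5 points (percentile 87.9), that of Hox and TALE genes -11.1 points (percentile 19.0) and that of housekeeping genes 0 points. For regions over 1 kb from a boundary the percentiles were 79.3, 63.8 and 3.04, by nearest boundary within 100 kb 51.5, 26.5 and 4.01, and with gene body plus 100 kb 97.2, 100 and 21.9. Among unmatched random lists they were 98.4, 99.9 and 2.68, so housekeeping genes then lay within the bounds. The remaining main lists stayed within the bounds. The differences were 40.0 points for HSC identity, 33.7 for lymphoid priming, 28.2 for megakaryocyte-erythroid, 31.8 for cell cycle and 24.1 for interferon response genes. With equal list lengths they were -4.29, 15.2, 2.04, 4.76 and 0 points, so that of HSC identity genes turned (percentile 15.1). Among their members, LT-HSC and MPP had 5 and 13 regions at Mecom, 6 and 11 at Meis1, 4 and 9 at the lymphoid factor gene Ikzf1, 4 and 9 at Fli1, 1 and 5 at the platelet glycoprotein gene Gp9, 4 and 10 at Cdk6 and 3 and 7 at Mcm5.

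**Figure D3:**
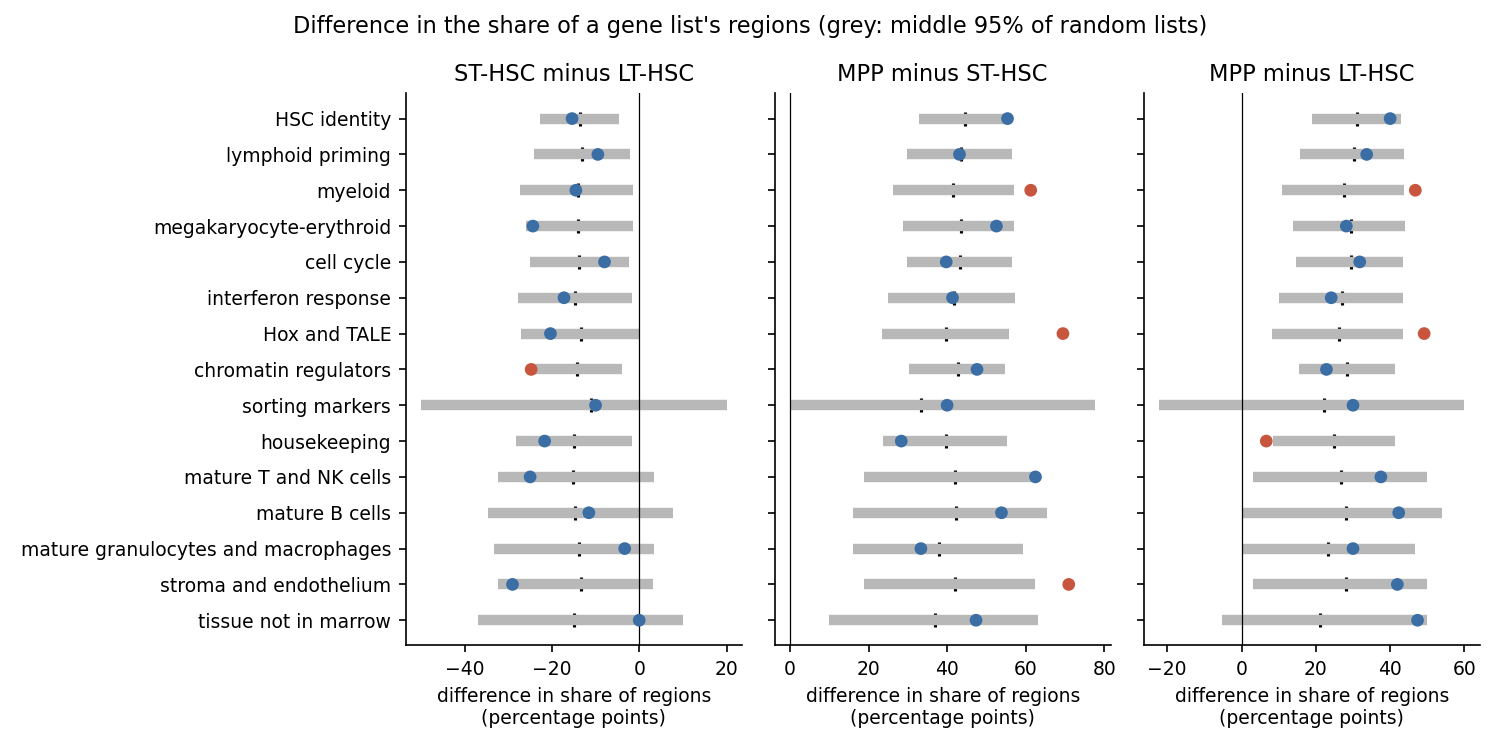
Difference between 2 populations in the share of a gene list's regions, in percentage points (horizontal axes), for the 15 gene lists (vertical axis) and the 3 pairs of populations (panels). Points are the observed differences (red where beyond the bounds), grey bars span the middle 95% of 10000 random lists and black ticks are their medians. Myeloid genes lie at 61.3 points between ST-HSC and MPP and at 46.8 points between LT-HSC and MPP.

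The genes of the sorting marker list had few regions. Kit had 1 region in LT-HSC, 0 in ST-HSC and 2 in MPP. Ly6a, which encodes Sca1, had 1, 0 and 1. Slamf1, which encodes CD150, had 1 region in each list, and Cd48 had 0, 1 and 1. Ptprc, the gene of CD45, which the labels do not name in the sort, had 3, 3 and 4. The regions of a single list with the highest values lay partly far from genes. In LT-HSC alone they were on chromosome 9 (3009956 to 3010107), 325 kb from Alkbh8, at a boundary of the zinc finger gene Zbtb20 (chromosome 16, 42875442 to 42875654) and on chromosome 17 (3080656 to 3080839), 34.2 kb from Scaf8. In ST-HSC alone they were at Zbtb20 (chromosome 16, 42875665 to 42875829), on chromosome 10 (22142482 to 22142634), 6.71 kb from E030030I06Rik, and at a boundary of Etfdh (chromosome 3, 79628725 to 79628969). The LT-HSC and ST-HSC regions at Zbtb20 are separate only because their intervals do not overlap. In MPP alone they were on chromosome 2 (22588859 to 22589011), 29.3 kb from Myo3a, chromosome 9 (3024404 to 3024595), 311 kb from Alkbh8, and chromosome 13 (74528913 to 74529074), 35.0 kb from Zfp825. The regions on chromosomes 2 and 9 belong to groups of regions with values over 1000.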

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

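Peaks on unplaced scaffolds were outside every gene comparison and are given here because their number is above 0. There were 74 in the LT-HSC list, 69 in the ST-HSC list and 68 in the MPP list. Of the tests below, the one on depth was chosen after its values were seen.

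The MPP list was the longest and held 14585 regions found in no other list. Deeper sequencing of the second MPP library is argued against as the cause. It would hold 0.483 times the tags of the second LT-HSC library (1.16 times in the first libraries). This holds if all values were scaled to the same total, which is not stated. Without that scale, counted in steps of the values, the median region found in all 3 lists held 0.810 times as many in the second MPP as in the second LT-HSC library, and 2.74 times in the first ones. A listed peak must be called in both libraries, but the second libraries alone do not set the list length. At least 44684 peaks were called in the second MPP and 40922 in the second LT-HSC library, against 150950 and 103783 in the first ones. An effect of depth in the first libraries therefore stays open. The calling threshold remains a candidate explanation. Among the top 20% of MPP peaks by value, 7.99% (exact 95% interval 7.36% to 8.67%) had no LT-HSC peak, against 87.2% in the lowest 20%. A true gain of weaker sites in MPP would give the same gradient and stays open, as untested. The libraries of a population also differed in how many calls they shared. At most 75.2% of the called peaks of the second MPP library were listed, against 54.5% in LT-HSC and 35.3% in ST-HSC. The part of this in the list lengths was not tested.

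A few regions had values far above all others, with 45 over 1000 in at least 1 library and peaks over 100 holding between 34.9% and 69.2% of a library's listed value. Of the 38 on placed chromosomes, 0 (0%, exact 95% interval 0% to 9.25%) lay within 1 kb of a gene boundary, against 55.0% of regions found in all 3 lists. This is consistent with reads from repeated sequence gathered at few positions, though mapping was not examined here. Ratios of MPP to LT-HSC, taken here without centring, differed between groups of these regions. They were 0.512 to 0.886 in 13 regions on chromosome 9 between 3000497 and 3035008 and 1.64 to 2.04 in 3 regions on chromosome 2 between 22587734 and 22589767. More than one source is therefore possible, and a difference between the populations stays open.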

How the results depend on the processing

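The numbers of peaks and the order of values by sharing class kept their size under all alternatives run. Overlap rule, peak width and autosomes alone moved no region count by over 1.5 times. The alternatives for value tests, boundary changes and pair overlap were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number. A block of column position, which is also the depth class, passed the regions given below. Deviations by column position correlated at r = 0.329 between LT-HSC and ST-HSC, 0.129 between ST-HSC and MPP and 0.277 between LT-HSC and MPP, a hint from the data and not the design. Neither library can be left out of a joint list, and the motif alternatives were not run for want of sequence. Where a value changed, the cause was not tested, except that shorter lists hold fewer regions.

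With the top 50% of each list, 7126 regions were in all 3 lists, 1351, 212 and 6751 in LT-HSC, ST-HSC and MPP alone, 3498 in LT-HSC not ST-HSC, 980 the reverse, 730 in ST-HSC not MPP, 8898 the reverse, 1869 in LT-HSC not MPP and 7519 the reverse. With the strongest 17249 peaks of each list, ST-HSC alone had 3054, MPP alone 3404, LT-HSC not ST-HSC 4909, ST-HSC and MPP 5160 each against the other and MPP not LT-HSC 5259. With pairs overlapping by at least 100 bp, 7470 were in all 3 lists. Shares near a gene boundary for the LT-HSC, ST-HSC and MPP lists, all 3, and LT-HSC, ST-HSC and MPP alone were 48.6%, 51.3%, 42.8%, 60.4%, 25.6%, 24.6% and 29.7% at 2 kb, 37.1%, 40.9%, 29.99%, 49.7%, 14.9%, 15.2% and 15.5% at 500 bp, and 37.4%, 40.6%, 30.0%, 49.9%, 15.4%, 14.4% and 15.6% with protein-coding genes only.

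In the share of list regions, the myeloid difference MPP minus ST-HSC was 53.2 points by nearest boundary within 100 kb, 21.9 with equal lists and 63.2 over 1 kb from a boundary, all within the bounds. MPP minus LT-HSC it was 33.9, 12.5 and 47.4, and 38.9 with gene body plus 100 kb. The megakaryocyte-erythroid difference ST-HSC minus LT-HSC passed at -27.3 by nearest boundary. Hox and TALE genes turned relative to random lists, MPP minus LT-HSC at 21.2 by nearest boundary and -11.1 with equal lists, and MPP minus ST-HSC at -5.56 with equal lists. Tissue not in marrow turned at 23.7 with gene body plus 100 kb. Of 225 such values 193 kept a call or the lack of one, 19 lost a call, 9 gained one and 4 turned with a call in either setting. Others without a call turned too, among them HSC identity at -4.29 (MPP minus LT-HSC, equal lists).

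Lymphoid genes with a boundary peak numbered 9 and 8 in LT-HSC and ST-HSC at 2 kb, and in MPP 7 at 500 bp and 7 with equal lists. With equal lists MPP had 4 myeloid and 3 megakaryocyte-erythroid genes. The lymphoid gain MPP minus LT-HSC was 5 at 2 kb and 2 at 500 bp, and the myeloid one 1 with equal lists, within the bounds. The myeloid gain MPP minus ST-HSC passed at 9 with 2 kb, and the interferon one fell to 1 with equal lists. Megakaryocyte-erythroid genes passed at -5 (ST-HSC minus LT-HSC, 2 kb) and turned to -4, beyond the bounds (MPP minus LT-HSC, equal lists).

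For values in shared regions, limma without a block passed 0. Quantile normalization passed 20 higher and 37 lower for MPP minus LT-HSC and 15 lower for MPP minus ST-HSC. The library block passed 56 and 62, and the 2 populations alone 110 and 332. Without the first ST-HSC library MPP minus LT-HSC had 110 higher and 335 lower. Without the second it had 100 and 343, and MPP minus ST-HSC 14 and 494. Leaving out any other library passed 0. A lone library is assumed to vary like the other groups.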

Other observations

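The tests on values and on the first principal component below were chosen after the files were seen. The lists of other marrow cells and tissues had few boundary peaks. Mature T and NK cell genes had them at 1 of 14 genes in LT-HSC, 1 in ST-HSC and 3 in MPP, where Cd5 and Gzmb were added to Cd3d. Mature B cell genes had 2, 1 and 2 of 9, mature granulocyte and macrophage genes 2, 1 and 2 of 15, and stroma and endothelium genes 1, 0 and 2 of 14. Hox and TALE genes had 4, 3 and 7 of 37, below nearly all random lists in MPP (percentile 0.04), with Hoxa3, Hoxa7 and Pbx2 found in MPP alone. Chromatin regulator genes had 17, 15 and 16 of 29, and interferon response genes 12, 10 and 16 of 19. In the regions of their windows, the lists not yet described differed between LT-HSC and MPP by 37.5 points for mature T and NK cells, 42.3 for mature B cells, 30.0 for mature granulocytes and macrophages, 41.9 for stroma and endothelium, 47.4 for tissue not in marrow, 22.9 for chromatin regulators and 30.0 for sorting markers, all within the bounds. Beyond them with equal list lengths were stroma and endothelium at 50.0 points (percentile 99.9) and chromatin regulators at -19.1 points (0.635), and for regions over 1 kb from a boundary mature B cells at 73.3 points (97.7).

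The values of the libraries were compared in 11947 regions found in all 3 lists. The lists were made separately, so values were centred per library first. With limma, Benjamini-Hochberg adjustment and no block, 0 regions passed in each of the 3 comparisons. At an unadjusted p under 0.05 there were 297 regions for ST-HSC minus LT-HSC, 1162 for MPP minus ST-HSC and 1441 for MPP minus LT-HSC, where 597 would be expected if none changed. With the column position of the library as a block, 56 regions were higher and 62 lower in MPP than LT-HSC, and 0 passed in the other comparisons. The ST-HSC libraries enter the shared spread. Without the first of them MPP minus LT-HSC passed 110 higher and 335 lower, without the second 100 and 343, and with MPP and LT-HSC alone 110 and 332. MPP minus ST-HSC passed 14 higher and 494 lower without the second ST-HSC library, where the lone ST-HSC library is assumed to vary like the others. In the fit with the block, the largest rises in MPP minus LT-HSC were 2.15 (log2) at a region on chromosome 1 (105435149 to 105435347) 78.3 kb from Rnf152, 2.13 on chromosome 6 (95334896 to 95335147) 138 kb from Suclg2, and 2.07 on chromosome 1 (14924949 to 14925171) 6.20 kb from Trpa1. The next were 1.95 at 30.3 kb from Socs6 and 1.87 at 5.29 kb from Rnf180. The largest falls in that comparison included -2.42 inside the transporter gene Slc22a3 (chromosome 17, 12427172 to 12427415), -2.20 and -2.09 near Gm39469 and -2.11 near Ndufb3. The adjusted p of these regions from limma with the block lay between 0.0271 and 0.0394, and without it between 0.0587 and 0.160. Some of these changes rest on values near the floor of a library, and so on few tags. At Slc22a3 the second MPP value was 4.04, where the lowest listed was 3.54. At Rnf152 and Socs6 the second LT-HSC values were 3.17 and 3.41, where the lowest listed was 2.68. Changes in the first libraries correlated across regions with those in the second with r = 0.467 for MPP minus LT-HSC, 0.319 for MPP minus ST-HSC and -0.026 for ST-HSC minus LT-HSC. No tested gene list passed with camera, with a preset or an estimated correlation. Sorting markers, stroma and endothelium, and tissue not in marrow had too few of these regions to be tested. The lowest camera p was 0.0375 for mature B cell genes in MPP minus LT-HSC (adjusted p = 0.450, and 0.790 with an estimated correlation), with a median log2 change of 0.27 over 8 regions, 7 of them above 0.

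In the same regions the MPP libraries stood apart from the LT-HSC libraries on the first principal component, which held 40.0% of the variance. MPP lay at 0.53 in both libraries, LT-HSC at -0.34 and -0.28, and ST-HSC at -0.50 and 0.06. The second component, with 25.7% of the variance, set the first libraries of LT-HSC, ST-HSC and MPP (0.425, 0.276 and 0.457) apart from the second ones (-0.530, -0.483 and -0.145). Column position is also the depth class, so an effect of depth on these values stays open there. For the first component alone, sequencing depth is argued against as the cause of the distance between MPP and LT-HSC. The libraries of MPP and of LT-HSC are several-fold apart in depth by the steps of their values. Yet within each population they lay at most 7.31% of that distance from each other. The ST-HSC libraries, also several-fold apart, lay 66.6% of that distance from each other, so an effect of depth on their place stays open. Signal within peaks could account for the distance between MPP and LT-HSC, because the 6 libraries took the order of their median value on the first component. Spearman rho was 1.00 (exact permutation p = 0.00278). Pearson r was 0.929 (exact permutation p = 0.0181), and 0.960 without the 2 libraries farthest from the median. The permutations treat the 6 libraries as exchangeable, though each population gave 2 of them. These p-values therefore do not separate signal from population. No other relation across libraries was computed. Across regions the second minus the first ST-HSC library correlated with MPP minus LT-HSC at r = 0.360 in first and 0.170 in second libraries. The MPP libraries have both the highest median values and the population's own chromatin, so a difference between populations stays open, as does a different mix of sorted cells in the second ST-HSC library.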
